A study of Pimephales promelas with 16 samples.

How the data were processed

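Total RNA of male liver was amplified, labelled with the dye Cy3 and hybridised to 1-colour Agilent oligonucleotide arrays, per the labels' protocols, which give a mean RNA integrity number of 7.6 over the samples and none for single samples. Scanner output of 16 arrays was used, 5 for the Platte River, 3 for the Elkhorn River, 3 for the Niobrara River and 5 for the Dismal River, with the river and its impact class taken from the labels. Per the file headers, the spot intensities were extracted with Agilent Feature Extraction 9.5.1.1. The processed signal it deposited in each file is an intensity from which background had been subtracted, with spatial and multiplicative detrending and surrogate values for spots near background, and it had not been normalized between arrays. The mean and local background intensities in the same files, per the file headers, are pixel values without correction. Flags of the scanner software (well above background, non-uniform or population outlier, saturated, surrogate used) were taken as deposited. Each array held 15744 spots, of which 536 were controls and 15208 were probes of 60 bases, each spotted once.

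A table of log2 values was deposited beside the scanner files, and the method by which the authors made it is not given in the sources used here. Each of its 16 columns followed the log2 processed signal of its own array (Pearson r of at least 0.996 across probes, and at most 0.973 with any other array), and its 30 missing values were the 30 spots with an outlier flag. The column medians lay between 4.46 and 4.62. The scale of this table is therefore taken as log2, while its centring and normalization between arrays stay unknown, and it was used only as an alternative.

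For the main result the processed signal was scaled to the 75th percentile of its array over the probes, and log2 was taken. Control spots and the 30 spots with an outlier flag were left out, and no processed signal was 0 or less. Probes well above background on at least 3 arrays were tested (9012, with 6196 left out). A linear model with a mean for each river was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the rivers shared 1 estimate of the spread. Contrasts compared the equally weighted means of the high-impact and the low-impact rivers and all 6 pairs of rivers, and a moderated F test was used for any difference among the rivers. P-values were adjusted by the Benjamini-Hochberg method within each contrast, at a threshold of 0.05. Errors of differences are standard errors of the moderated fit. Where a probe was not well above background on any array of the dimmer group, the fold is given as a lower bound on the processed signal, the mean of the brighter group against, per array of the dimmer group, the higher of the lowest signal among probes well above background and the signal of the probe itself. The bound was also used for 5 named probes that were well above background on only some arrays of the dimmer group, with the signal itself on those arrays. No array was a duplicate of another (highest r between arrays 0.975 over 5806 probes).

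The fit was tested on simulated arrays made from the means and spreads of the 9012 probes, with 100 probes changed 2-fold and 100 changed 4-fold in each comparison. Between the impact classes, 85 of those changed 4-fold and 23 of those changed 2-fold were recovered, with 3 false calls. In Platte against Dismal it was 79 and 16, in Platte against Niobrara 72 and 10, in Elkhorn against Niobrara 45 and 0, in Elkhorn against Dismal 62 and 10, in Platte against Elkhorn 62 and 10, and in Niobrara against Dismal 60 and 3. Of the false calls no comparison had more than 7. The simulated noise was normal and independent between probes, with no effect shared by the probes of an array. These counts therefore do not measure the false calls on the real arrays.

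Per the file headers, the arrays lay on 3 slides, and each slide was scanned once, so that slide and scan were 1 batch. Slide 1 held 2 Platte, 2 Elkhorn and 2 Dismal arrays, slide 2 held 2 Platte, 2 Niobrara and 1 Dismal array, and slide 3 held 1 Platte, 1 Elkhorn, 1 Niobrara and 2 Dismal arrays. Counts were also computed with the slide as a fixed block and within each slide.

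The rule for naming genes, written before the data were examined, took described genes with the largest changes past the threshold (10 rises and 10 falls between the classes among probes whose river means were split by class, and 5 and 5 in each pair of rivers). It also fixed lists of genes for liver functions and for markers of other cell types. Every probe in the scanner files is called unknown, and the table of genes used here holds no sequences, so no probe could be matched to a gene, no gene was named by the rule, and no list was tested. In its place the 2 largest rises and the 2 largest falls of each comparison are given by identifier and sequence, ranked in the same way. Their genomic positions are not given in the sources used here.

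Alternatives written before the data were examined were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, the deposited table, no filter on dim probes, only probes well above background on all 16 arrays, the slide and the replicate number as blocks, each array left out in turn, the river as a random block, the classes compared without river terms, and only the arrays of the rivers compared. Added after the data had been seen were the log2 75th percentile of the array as a covariate, a fit without Elkhorn replicates 2 and 3, fits without other pairs of Elkhorn or Niobrara arrays, removal of the trend with probe GC content within each array, and every choice of 3 Platte arrays.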

Results

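Liver RNA was measured in adult male fathead minnows (Pimephales promelas), a small North American cyprinid widely used in aquatic toxicology, that had been held in cages for 7 days in 4 rivers of Nebraska. The labels class the Platte and Elkhorn Rivers as agricultural sites of high impact and the Niobrara and Dismal Rivers as agricultural sites of low impact. The labels give 3 cages per site, which held 15 females and 21 males, 36 fish in all. Livers of 5 Platte, 3 Elkhorn, 3 Niobrara and 5 Dismal males were hybridised, 1 array per sample. The labels do not say which cage a fish came from, so p-values measure the spread between these samples. Each of the 16 arrays carried 15208 probes of 60 bases, of which between 7024 and 8915 (46.2% to 58.6%) gave a signal well above background on an array. The 75th percentile of the signal lay between 182 and 320 on 14 arrays, and at 638 and 508 on Elkhorn replicates 2 and 3. In all, 9012 probes were well above background on at least 3 arrays and were tested. The number of arrays limits the precision of every comparison. The files used here do not pair the probes with genes, so that results are given by probe identifier and sequence. For each comparison at most 2 probes that rose and 2 that fell are named, and these were chosen after their values were seen. Levels are log2 signals relative to the 75th percentile of the array, and differences are first-named minus second-named river.

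The first question was whether hepatic expression differed between the high-impact and the low-impact rivers. In the high-impact rivers 219 probes were higher and 239 lower than in the low-impact rivers (limma, adjusted p under 0.05), 458 in all or 5.08% of those tested. Of these, 311 differed by at least 2-fold, and the median size of the difference was 1.22 on the log2 scale. At an unadjusted p under 0.05 there were 2014 probes, against 450.6 expected by chance. For 453 of the 458 probes both high-impact river means lay on the same side of both low-impact river means. On 118 of them all 8 high-impact arrays lay above, or all below, all 8 low-impact arrays. A further 6 tested probes separated in this way without passing the threshold, and chance gives 1.40 such probes in all (0.0155% per probe) if fish are exchangeable across rivers. Differences between rivers unrelated to class would raise that number, so it does not test the class.

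**Figure D1:**
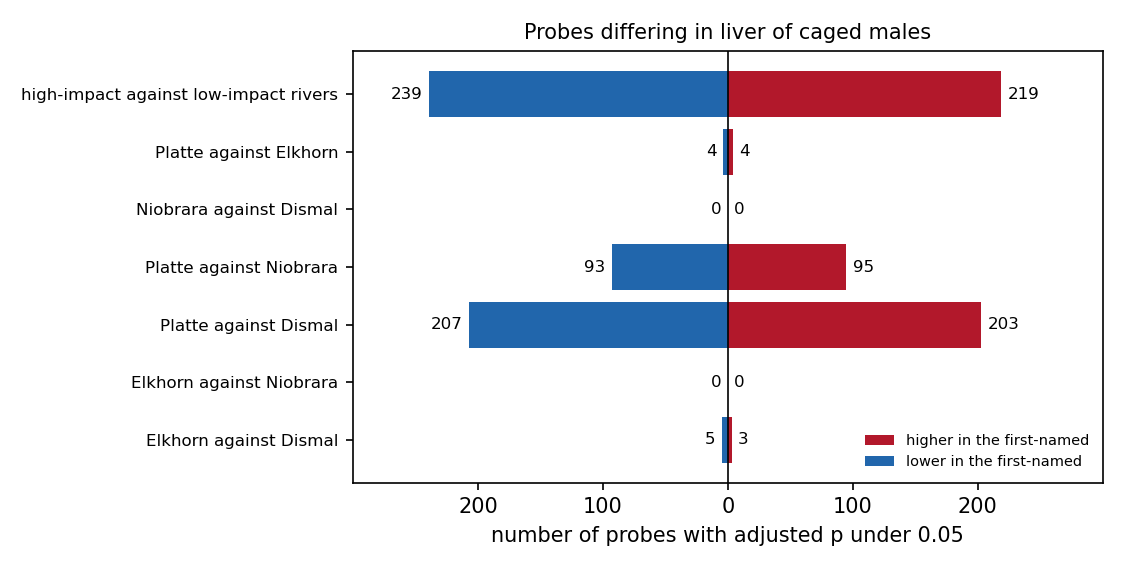
Number of probes with an adjusted p under 0.05 in each comparison (horizontal axis), with bars to the right for probes higher in the first-named river or class and bars to the left for probes lower there. The high-impact against low-impact comparison has 219 higher and 239 lower probes, and Niobrara against Dismal has none.

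The largest fitted rise among the probes whose river means were split by class was that of EA_Pp_57551a (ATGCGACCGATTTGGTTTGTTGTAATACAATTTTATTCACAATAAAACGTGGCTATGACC). Its level was 1.62 ± 0.95 (SD, n = 5) in Platte and 1.23 ± 1.48 (n = 3) in Elkhorn fish, against −2.33 ± 1.87 (n = 3) in Niobrara and −1.84 ± 0.90 (n = 5) in Dismal fish. The fitted difference between the classes was 3.51 ± 0.58 (SE; limma adjusted p = 0.00426), at least 10.8-fold on the processed signal since Niobrara replicate 2 was not well above background, and all 8 high-impact fish lay above the low-impact mean. EA_Pp_55594a (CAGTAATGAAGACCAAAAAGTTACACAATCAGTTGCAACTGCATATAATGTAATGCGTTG) was higher by 3.41 ± 0.52 (10.6-fold; limma adjusted p = 0.00367), again on all 8 high-impact arrays. Both calls held under each of the alternatives computed for them and without any single array. Their sizes did not: with normexp and quantile normalization, which adds an offset to every signal, the differences were 2.19 and 2.40, the first smaller than its bound, and that of EA_Pp_57551a was 4.20 with the brightness of the array as a covariate and 4.18 without both of the brightest arrays. The largest fitted falls, ranked by differences that reach below background, were in probes that were well above background on none of the 8 high-impact arrays, so that their folds are lower bounds on the processed signal. EA_Pp_52740a (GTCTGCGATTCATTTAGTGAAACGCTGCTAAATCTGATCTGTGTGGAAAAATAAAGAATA) was well above background in 6 of the 8 low-impact fish and at least 7.00-fold lower in the high-impact fish (limma adjusted p = 0.0161). Its call held without any single array, while its fitted difference then lay between −5.56 and −4.10. EA_Pp_70973a (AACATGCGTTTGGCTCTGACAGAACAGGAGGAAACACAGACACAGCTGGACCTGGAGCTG) was measured in 5 of the 8 low-impact fish, all 3 from the Niobrara and 2 from the Dismal, and was at least 13.5-fold lower (limma adjusted p = 0.0279). The call of EA_Pp_70973a was lost without Elkhorn replicate 2 or 3 or Niobrara replicate 1 or 3, each left out alone (adjusted p between 0.0545 and 0.0776), and with the brightness of the array as a covariate (adjusted p = 0.0946), where its fitted difference was −3.64. Without both of the brightest arrays, Elkhorn replicates 2 and 3, the calls of EA_Pp_52740a and EA_Pp_70973a ended (adjusted p = 0.135 and 0.180, limma), while their fitted differences were −4.42 and −4.08, against −4.67 and −4.51 before. With normexp and quantile normalization the differences of EA_Pp_52740a and EA_Pp_70973a were −1.48 and −1.93, smaller than these bounds, and both were still called. Among all probes called higher, 29 were well above background on no low-impact array, and among those called lower, 7 were so on no high-impact array.

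**Figure D2:**
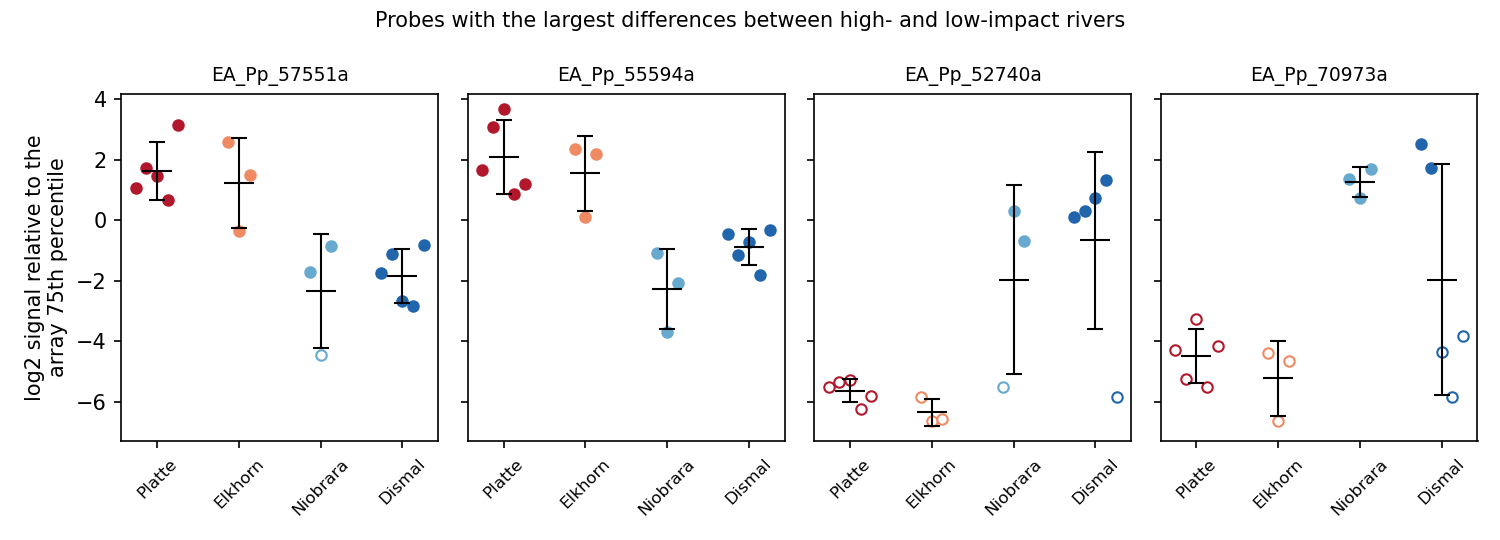
Log2 signal relative to the 75th percentile of the array (vertical axis) of 4 probes in each fish, by river. Filled points are well above background and open points are not, and bars give the river mean and SD. EA_Pp_57551a and EA_Pp_55594a are higher in Platte and Elkhorn fish, while EA_Pp_52740a and EA_Pp_70973a are well above background in none of them.

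The arrays lay on 3 slides, each scanned once, and every slide held fish of both classes. With the slide as a block 238 probes differed between the classes, 118 higher and 120 lower, and 221 of the 458 were still called in the same direction. Fitted within slides, 11 probes were called on slide 1 (4 against 2 arrays), none on slide 2 (2 against 3) and none on slide 3 (2 against 3), where limma gave 1823, 659 and 679 probes at an unadjusted p under 0.05. The difference of the 458 probes had the same direction on slide 1 for all of them, on slide 2 for 455 and on slide 3 for 457, although these arrays were also those that selected the probes. The count was 815 without Elkhorn replicate 1, 229 without Elkhorn replicate 2, 260 without Elkhorn replicate 3 and 302 without Niobrara replicate 3, and it was 106 without both of the brightest arrays (Elkhorn replicates 2 and 3). Each other pair of Elkhorn or Niobrara arrays left out, which also leaves 1 array in a river, lowered the count too, by unlike amounts. With 2 rivers in each class, fish of a river are not independent replicates of the class, and other features of the rivers were not separated from it.

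The 4 rivers can be paired in 3 ways, and the other pairings gave no called probe. Platte and Niobrara against Elkhorn and Dismal gave 677 probes at an unadjusted p under 0.05, and Platte and Dismal against Elkhorn and Niobrara gave 670 (limma, 0 past the threshold in both). To compare the high-impact rivers without shared arrays, probes called in a comparison of Platte with 1 low-impact river were read in Elkhorn against the other. Of the 410 probes that differed between Platte and Dismal, 352 (85.9%) had the same direction in Elkhorn against Niobrara, with a median difference of 1.51 in the first and 0.65 in the second. None of the other assignments of the Elkhorn and Niobrara fish reached more than 78.0%, but with 20 assignments a one-sided exact permutation p of 0.05 was the smallest possible. Of the 188 probes that differed between Platte and Niobrara, 168 (89.4%) had the same direction in Elkhorn against Dismal, with medians of 1.77 and 0.80 (one-sided exact permutation p = 0.0179 over 56 assignments, highest other 88.8%). With the slide as a block the shares were 82.5% of 280 probes and 89.6% of 77 probes. The second had p = 0.0364 (exact, 2 of 55 assignments as large, the real 1 included). The first rests on Elkhorn replicate 1 against Niobrara replicate 3 alone, since only slide 3 held both rivers. The real assignment therefore shared its contrast with another, so p = 0.1 (exact, 2 of 20) was the smallest possible. It decides nothing.

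**Figure D3:**
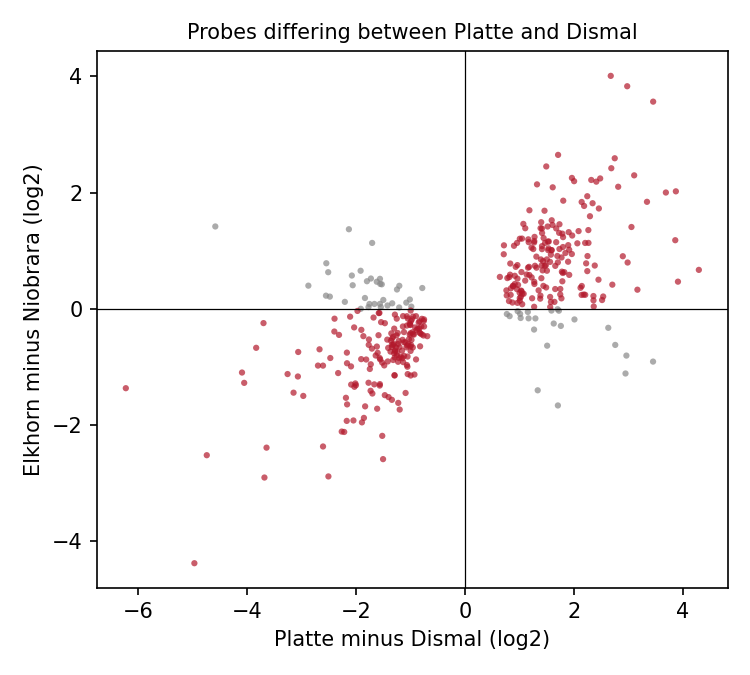
Difference between Elkhorn and Niobrara fish (vertical axis, log2) against the difference between Platte and Dismal fish (horizontal axis, log2) for the 410 probes called in Platte against Dismal. Each point is a probe, red where both differences have the same sign (352 probes) and grey where they do not, and no array enters both axes.

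Platte fish differed from the fish of either low-impact river. Against Dismal fish 203 probes were higher and 207 lower (limma, adjusted p under 0.05). The largest fitted rises were those of EA_Pp_59715a and EA_Pp_65209a. EA_Pp_59715a (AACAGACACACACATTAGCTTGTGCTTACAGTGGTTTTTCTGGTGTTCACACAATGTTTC) was higher in Platte by 4.30 ± 0.94 (19.6-fold; limma adjusted p = 0.0202), with a call that ended without Platte replicate 2 or Dismal replicate 2 (adjusted p = 0.0521 and 0.0525) and a difference of 3.55 with normexp and quantile normalization. EA_Pp_65209a (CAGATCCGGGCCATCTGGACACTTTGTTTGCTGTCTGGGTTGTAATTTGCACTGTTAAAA) was at 9.82 ± 0.44 (n = 5) in Platte, 7.74 ± 0.54 (n = 3) in Elkhorn, 7.27 ± 0.88 (n = 3) in Niobrara and 5.90 ± 1.78 (n = 5) in Dismal fish. Its difference between Platte and Dismal was 3.91 ± 0.67 (15.1-fold; limma adjusted p = 0.00491), and its call held without any single array, although the difference was 3.19 without Dismal replicate 3. EA_Pp_59748a (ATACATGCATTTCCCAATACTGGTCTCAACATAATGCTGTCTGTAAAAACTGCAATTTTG) differed between Platte and Dismal by −6.22 ± 1.53, at 0.51 ± 3.45 (n = 5) against 6.73 ± 0.87 (n = 5) in Dismal fish (at least 57.3-fold; limma adjusted p = 0.0327). The difference was −4.69 without Platte replicate 1, the only Platte fish in which the probe was not well above background, and −5.19 with normexp and quantile normalization, smaller than the bound. This call ended without any 1 of 6 arrays, which were Platte replicates 2 and 3 and Dismal replicates 1, 2, 3 and 5 (adjusted p between 0.0510 and 0.0722), and with the replicate number as a block. EA_Pp_52740a, already named, was at least 8.79-fold lower in Platte than in Dismal fish (limma adjusted p = 0.0325), and the call ended for 9 of the 16 arrays left out in turn, the 5 of Platte and Dismal replicates 1 to 4 (adjusted p up to 0.0829), as it did with the slide as a block (adjusted p = 0.0596), where the fitted difference was −5.02 against −4.97 before. With 1 array left out that difference lay between −6.26 and −4.47. With normexp and quantile normalization it was −1.84, smaller than the bound, and still called. In all, 280 probes differed with the slide as a block. Slide 1 gave 6 calls on its own (2 against 2 arrays), and the other slides each held a single array of 1 of the rivers. The count was 190 and 269 without Platte replicates 2 and 3, and 226 and 203 without Dismal replicates 2 and 3.

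Against Niobrara fish 95 probes were higher and 93 lower in Platte fish. EA_Pp_62204a (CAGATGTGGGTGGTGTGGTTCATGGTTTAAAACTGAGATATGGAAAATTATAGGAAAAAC) was well above background in all 5 Platte and 1 of 3 Niobrara fish and at least 20.6-fold higher in Platte (limma adjusted p = 0.0457). Its fitted difference was 5.69, and it was 4.94, 4.82 and 7.32 without Niobrara replicates 1, 2 and 3. EA_Pp_68272a (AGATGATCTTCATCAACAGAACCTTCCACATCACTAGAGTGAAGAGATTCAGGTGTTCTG) was well above background in no Niobrara fish and at least 5.11-fold higher in Platte fish (limma adjusted p = 0.0325). EA_Pp_63752a (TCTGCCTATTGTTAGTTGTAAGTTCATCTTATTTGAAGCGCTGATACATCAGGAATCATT) was well above background in none of the 5 Platte fish and in all 3 Niobrara fish, and was at least 4.27-fold lower (limma adjusted p = 0.0404). EA_Pp_53797a (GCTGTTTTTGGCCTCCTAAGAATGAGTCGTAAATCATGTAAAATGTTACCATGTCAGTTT) was likewise measured in all 3 Niobrara and no Platte fish, and was at least 5.55-fold lower (limma adjusted p = 0.0116). The call of EA_Pp_53797a held with the slide as a block and ended without Niobrara replicate 2 (limma adjusted p = 0.0555). The other 3 calls ended with the slide as a block (limma adjusted p = 0.117, 0.0591 and 0.0871, in the order named), where the fitted differences were 5.31, 4.53 and −3.82 against 5.69, 4.60 and −4.19 before, and for 12, 7 and 9 of the 16 arrays left out in turn. With normexp and quantile normalization the differences of EA_Pp_68272a and EA_Pp_63752a were 1.11 and −0.87 and were no longer called, while that of EA_Pp_53797a was −0.94 and still called, all smaller than the bounds on the processed signal. That of EA_Pp_62204a was then 2.74, also smaller than its bound, and called. Without a filter on dim probes, and with the replicate number as a block, the calls of EA_Pp_62204a and EA_Pp_63752a ended. With the slide as a block 77 probes differed, 33 higher and 44 lower, and slide 2 alone gave none (limma, 2 against 2 arrays, 614 at an unadjusted p under 0.05), while slide 3 held a single array of each river. Without Platte replicates 2 and 3 the count was 96 and 103, and without Niobrara replicates 1, 2 and 3 it was 61, 49 and 87.

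Elkhorn fish gave fewer calls against the same rivers. No probe differed between Elkhorn and Niobrara fish (limma, smallest adjusted p = 0.0581), although 1094 had an unadjusted p under 0.05. Against Dismal fish 3 probes were higher and 5 lower. EA_Pp_60842a (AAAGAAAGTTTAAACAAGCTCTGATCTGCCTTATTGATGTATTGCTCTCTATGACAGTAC) was higher in Elkhorn by 2.19 ± 0.34 (4.56-fold; limma adjusted p = 0.0255), at 0.33 ± 0.64 (n = 3) against −1.86 ± 0.24 (n = 5), and the Platte level was 0.83 ± 0.58 (n = 5). EA_Pp_63882a (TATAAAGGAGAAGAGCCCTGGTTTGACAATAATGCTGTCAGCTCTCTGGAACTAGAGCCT) was at least 9.06-fold higher (fitted difference 3.20 ± 0.56; limma adjusted p = 0.0441), since Dismal replicate 2 was not well above background. EA_Pp_50630a (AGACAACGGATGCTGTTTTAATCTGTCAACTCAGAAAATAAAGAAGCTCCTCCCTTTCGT) was well above background in all 5 Dismal and 1 of 3 Elkhorn fish and at least 153.6-fold lower in Elkhorn (limma adjusted p = 0.0330). With normexp and quantile normalization its difference was −4.12, smaller than that bound, and not called. EA_Pp_53729a (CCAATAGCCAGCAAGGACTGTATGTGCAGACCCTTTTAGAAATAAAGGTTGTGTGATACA) was well above background in 2 of 5 Dismal and no Elkhorn fish, at least 1.83-fold lower (limma adjusted p = 0.0330). These 4 calls ended for 5, 10, 7 and 6 of the 16 arrays left out in turn. They also ended with the replicate number as a block, with brightness as a covariate and with the slide as a block (limma adjusted p between 0.0720 and 0.107), where the fitted differences were 2.12, 2.98, −7.49 and −2.65 against 2.19, 3.20, −7.38 and −2.76 before. That block left 2 probes, both lower in Elkhorn. The differences of EA_Pp_63882a and EA_Pp_53729a were 1.77 and −0.26 with normexp and quantile normalization, and neither was called, while that of EA_Pp_60842a was 1.31 and called. The call of EA_Pp_63882a also ended without a filter on dim probes, and that of EA_Pp_53729a under quantile normalization. Without both of the brightest arrays Elkhorn was a single array, assumed to vary like the other rivers, and 5 probes differed, none of them among the 8. Slide 1 alone gave 42 calls (2 against 2 arrays), and slide 3 held a single Elkhorn array.

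Elkhorn replicate 1 moved the Elkhorn counts most. Without it 201 probes differed between Elkhorn and Niobrara, 328 between Elkhorn and Dismal and 134 between Platte and Elkhorn, and the Elkhorn group then consisted of the 2 brightest arrays, both on slide 1. Left out alone, 7 other arrays gave between 1 and 4 probes in Elkhorn against Niobrara (Platte replicates 3, 4 and 5, Elkhorn replicate 3, Niobrara replicate 3 and Dismal replicates 3 and 5). In Elkhorn against Dismal the count was 15 without Platte replicate 5, 2 without Elkhorn replicate 2 or 3, 1 without Dismal replicate 1 or 2 and 3 without Dismal replicate 4. Elkhorn was represented by fewer fish than Platte. With each choice of 3 of the 5 Platte arrays, between 16 and 112 probes differed from Niobrara (median 59.5 over 10 choices) and between 109 and 290 from Dismal (median 141.5). The difference between the high-impact rivers was tested directly in the comparison that follows.

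Platte and Elkhorn fish differed in 8 probes, 4 higher and 4 lower in Platte (limma, adjusted p under 0.05), with 917 at an unadjusted p under 0.05. EA_Pp_61805a (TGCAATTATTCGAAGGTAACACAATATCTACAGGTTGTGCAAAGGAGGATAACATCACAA) was well above background in all 5 Platte and no Elkhorn fish, at least 4.57-fold higher in Platte. EA_Pp_50646a (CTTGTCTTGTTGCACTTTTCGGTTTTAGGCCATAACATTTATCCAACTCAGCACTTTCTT) was higher in Platte by 3.54 ± 0.59 (11.6-fold), at 2.62 ± 0.53 (n = 5) against −0.93 ± 0.87 (n = 3). EA_Pp_63752a and EA_Pp_67165a (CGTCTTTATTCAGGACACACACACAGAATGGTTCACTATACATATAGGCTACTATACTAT) were well above background in all 3 Elkhorn and no Platte fish, at least 11.4-fold and 8.46-fold lower in Platte. All 4 had a limma adjusted p of 0.0416. No probe was called with the slide as a block, where the limma adjusted p of all 4 was 0.0842 and the fitted differences were 4.53, 3.62, −5.72 and −5.29, against 4.17, 3.54, −5.61 and −4.96 before. Slide 1 alone gave 20 calls (2 against 2 arrays), and slide 3 held a single array of each river. With normexp and quantile normalization the differences were 0.63, 2.73, −1.72 and −1.32, all below the folds given, and none of the 4 was called. With Elkhorn a single array, without the 2 brightest, 5 probes differed, none of which was among the 8. Each of the 4 calls ended for 12 or 13 of the 16 arrays left out in turn, and the count then ranged from 0 to 134 and stayed within 1.5 times of 8 only without Dismal replicate 5. The difference of EA_Pp_67165a then lay between −5.68 and −4.39. Under quantile normalization the only call was a probe lower in Platte, as it was in the deposited values, and normexp with quantile normalization gave 2, both lower.

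Niobrara and Dismal fish did not differ in any probe (limma, smallest adjusted p = 0.623), and the 445 probes at an unadjusted p under 0.05 were about the 450.6 expected by chance. In simulated arrays with the same numbers of fish, 60 of 100 probes changed 4-fold and 3 of 100 changed 2-fold were recovered in this comparison, so that changes of 2-fold would mostly have been missed. With the slide as a block the count was again 0, and slides 2 and 3 each held a single array of 1 of these rivers. It was 5 without Niobrara replicate 3 and 1 without Dismal replicate 5.

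A difference among the 4 rivers of any kind was found for 240 probes (moderated F test of limma, adjusted p under 0.05), and for 145 with the slide as a block. The count was 540 without Elkhorn replicate 1, 136, 128 and 158 without Platte replicates 2, 3 and 4, and 158 without either Dismal replicate 2 or 3. Over the 5806 probes well above background on every array, the profiles of fish from the same river correlated with a mean r of 0.944 across probes, those from different rivers of the same class with 0.937, and those from rivers of different class with 0.924. Probes are not independent replicates. Over all pairs of fish the mean within classes exceeded that between classes by 0.0166 (one-sided exact permutation p = 0.000155 over 12870 assignments of fish). Because the within-class mean includes fish of the same river and fish were assigned across rivers, this p does not separate class from river, and the rivers themselves allow only 3 pairings. By river, the mean r was 0.952 within Dismal, 0.945 within Platte, 0.939 within Niobrara and 0.919 within Elkhorn, and it was 0.946 between Niobrara and Dismal. The other pairs of rivers lay close together, at 0.927 for Platte with Elkhorn, 0.927 for Platte with Dismal, 0.923 for Platte with Niobrara, 0.922 for Elkhorn with Dismal and 0.918 for Elkhorn with Niobrara. The higher mean between different rivers of the same class (0.937 against 0.924) thus came mostly from the low-impact pair.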

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

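The search for probes with a gap between fish, their relation to river and slide and the sharing of patterns between probes were tests chosen only after results had been seen, while that of neighbouring spots was written before its result. In the rivers with 5 arrays, each named probe and 3 measures of array quality were searched for a fish far from the other 4, in 42 sets of 5 values. Dixon's ratio passed its 95% value in 6 sets, where chance gives about 1 in 20, or 2.10. EA_Pp_52740a was at −5.83 in Dismal replicate 5 and between 0.12 and 1.32 in the other Dismal fish. EA_Pp_63752a was at −5.47 in Dismal replicate 1, against −0.83 to 0.09. EA_Pp_68272a was at −6.32 in Dismal replicate 5, against −1.47 to 0.17. EA_Pp_59748a was at −5.64 in Platte replicate 1, against 1.69 to 2.51 in the other Platte fish. In the same probe Dismal replicate 4 was at 5.21, against 6.83 to 7.29. EA_Pp_59715a was at 1.86 in Platte replicate 4, against 4.16 to 4.51. In the first 4 of these the outlying spot was not well above background while the spots of the other 4 fish of that river were.

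The same kind of behaviour was then searched for among all tested probes. Those found include EA_Pp_52740a, EA_Pp_63752a and EA_Pp_68272a from above, and EA_Pp_62204a and EA_Pp_70973a, named earlier. In 52 tested probes the 16 sorted values had a gap of at least 8-fold with at least 2 fish on each side, all fish below it not well above background and all fish above it well above background, and 24 and 10 probes had gaps of at least 4 and 5 on the log2 scale. The 2 widest gaps, chosen after their values were seen, were those of EA_Pp_59353a (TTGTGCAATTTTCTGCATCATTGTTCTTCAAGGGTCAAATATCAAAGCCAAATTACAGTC), with 6 fish between 3.56 and 6.30 and 10 between −6.77 and −5.49, and EA_Pp_60408a (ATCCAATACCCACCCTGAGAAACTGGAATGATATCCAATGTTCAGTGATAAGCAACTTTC), with 5 fish between 4.99 and 8.38 and 11 between −6.14 and −3.62. Of the 52 probes 3 differed between the impact classes, EA_Pp_52740a and EA_Pp_70973a among them. By Fisher's exact test 9 had a p under 0.05 with the river and 3 with the slide, where chance gives at most 2.60, and none passed after adjustment over the 52.

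Local damage of the array would lower the spots around an off spot too, and the median deviation of those neighbours from their river means was −0.0107 (353 off spots, a median of 8 neighbours each), against −1.63 for the off spots themselves, which argues against such damage. A single programme of expression switched on in some fish would give the probes a common pattern. The median absolute correlation between the patterns was 0.218, against a mean of 0.187 in 1000 shuffles. Of these 119 gave as large a value, and their highest was also 0.218, so weak sharing between probes is not excluded. No array had fewer than 32.7% or more than 53.8% of these probes off. Together these values argue against a single programme. An inherited difference in the sequence under the probe, or in the presence of the gene, may give such patterns, of which 50 were distinct. It cannot be told apart here from expression that differs between single fish, because no genotypes were used and each fish was measured once.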

How the results depend on the processing

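Array brightness, GC content, pairs of arrays left out and choices of 3 Platte arrays were alternatives chosen after seeing the data. The high-impact against low-impact count stayed within 1.5 times of 458 under both quantile normalizations, the deposited values, both filters on dim probes, the river as a random block (604), no river terms (580), the brightness covariate (359) and GC removal (458). The random block had an estimated correlation within rivers of −0.00368. It thus treated fish nearly as independent replicates of the class, as the fit without river terms did, and does not allow for differences between rivers. It was 238 with the slide as a block. It was 106 without the 2 brightest arrays (Elkhorn replicates 2 and 3), 170 without Elkhorn replicates 1 and 2, 435 without Elkhorn replicates 1 and 3, and 81, 249 and 59 without Niobrara replicates 1 and 2, 1 and 3, and 2 and 3, so that the number of fish alone does not account for the falls.

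With the slide as a block, Platte against Elkhorn gave 0 probes, Platte against Niobrara 77, Elkhorn against Dismal 2 and any difference 145. With normexp and quantile normalization, Platte against Elkhorn gave 2 and Elkhorn against Niobrara 1. Quantile normalization alone gave 1 and 2 for these comparisons, and so did the deposited values. Without a filter on dim probes Platte against Niobrara gave 117, and the median over all probes then moved to −0.20 between the classes, −0.29 in Elkhorn against Niobrara, −0.30 in Elkhorn against Dismal and 0.24 in Platte against Elkhorn. With only probes well above background on all 16 arrays, Platte against Elkhorn gave 3, Elkhorn against Niobrara 1 and Elkhorn against Dismal 4. The brightness covariate gave 0 for Platte against Elkhorn and lowered Elkhorn against Dismal from 8 to 6. It raised Platte against Niobrara from 188 to 265 and Platte against Dismal from 410 to 570. Without the 2 brightest arrays, which leaves Elkhorn with 1 array that is assumed to vary like the other rivers, Platte against Elkhorn gave 5, Elkhorn against Niobrara 4 and Elkhorn against Dismal 5. Fitting only the arrays of the rivers compared gave 2 for Niobrara against Dismal, 70 for Platte against Niobrara, 6 for Elkhorn against Niobrara and 16 for Elkhorn against Dismal. With 3 Platte arrays Platte against Niobrara gave 16 to 112 (median 59.5), and Platte against Dismal 109 to 290 (median 141.5). The cause of these changes was not tested.

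The labels number the fish of each river. Same-numbered fish showed little shared deviation, and no chance value was computed for it. The mean correlation of their deviations was 0.0379 over 20 pairs, 8 of them above 0.1, against −0.0100 for other pairs, and 5 of the 16 fish correlated best with their own number. With the replicate number as a block (replicate block) Platte against Elkhorn and Elkhorn against Dismal gave 0, Platte against Niobrara 58 and any difference 125, and no other count moved by over 1.5 times.

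With each array left out in turn, the counts ranged from 229 to 815 between the classes, 0 to 134 for Platte against Elkhorn, 0 to 5 for Niobrara against Dismal, 49 to 212 for Platte against Niobrara, 190 to 472 for Platte against Dismal, 0 to 201 for Elkhorn against Niobrara, 1 to 328 for Elkhorn against Dismal and 128 to 540 for any difference. The highest values were those without Elkhorn replicate 1, except for Platte against Niobrara (Elkhorn replicate 2) and Niobrara against Dismal (Niobrara replicate 3). Of 320 differences of named probes with an array left out, 191 stayed called, 129 kept their direction without passing the threshold and none reversed. Under the other alternatives it was 122, 63 and 0 of 185. Signal over background limits the dimmer probes, since 6196 were not tested. The fixed gene lists could not be tested and their alternatives were not run, because no probe was paired with a gene.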

Other observations

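The tests in this part were chosen after the results had been seen, except the other splits of the arrays and the use of the slide as a block. Of 100 splits of the 16 arrays into groups of the same sizes, only the real 1 gave as many as its 458 probes, which argues against a chance split of single fish (1% was the smallest share possible). These splits exchange fish between rivers and do not test the class against the rivers. The highest other split gave 267, and it set 7 of the low-impact fish and Elkhorn replicate 1 against the others, close to the real split. With the slide as a block 221 of the 458 probes were still called, and the 237 others kept their direction, with a median log2 difference of 1.05 before and 1.00 after and a median standard error of 0.257 before and 0.280 after. The residual degrees of freedom fell from 12 to 10, and the shares of these changes in the lost calls were not separated. With array brightness as a covariate 245 were still called, and in the 213 others the difference fell from a median of 1.07 to 0.92 and the error rose from 0.267 to 0.281. Without the 2 brightest arrays, which leaves Elkhorn with 1, 79 were still called, and in the 379 others the difference fell from 1.18 to 0.97 and the error rose from 0.260 to 0.319, while leaving out pairs of Niobrara arrays gave 59, 81 and 249 probes in all, and Elkhorn replicates 1 and 2 and 1 and 3 gave 170 and 435, against 106. A trend on GC content would move called probes of like GC content 1 way. Of the called probes 57.0% went the majority way of their GC bin (6 bins), against 54.3% after shuffling (34 of 1000 shuffles as large). With the trend removed within arrays, 439 of the 458 were still called. The median difference over the 458 was 1.22 before and after, which argues against such a trend as the cause of most of the calls. These values argue against slide, brightness or GC content as the whole cause, and leave each open as part of it.

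A difference of Platte alone is argued against by the probes called in Platte against Niobrara, which went the same way in Elkhorn against Dismal in 89.4% of cases, more often than under any other assignment of those fish, though by little (highest other 88.8%; p = 0.0179, exact). The p was 0.0364 with the slide as a block (89.6%, exact), where 2 of 55 assignments, the real 1 included, gave as large a share. The probes called in Platte against Dismal, read in Elkhorn against Niobrara, gave p = 0.05 (exact), the smallest possible there. With the slide as a block that reading compared 1 Elkhorn array with 1 Niobrara array. There p = 0.1 (exact) was the smallest possible, so it cannot decide. The evidence against Platte alone is thus limited. In both readings the choice of probes was not repeated for the other assignments. A candidate explanation is a difference shared by the high-impact rivers, and the agricultural impact named by the labels stays untested as its cause. It cannot be told apart from other differences between single rivers, since the other pairings of the 4 rivers gave 0 called probes but only 3 pairings exist.

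For Platte against Niobrara the real split was the only 1 of 56 with as many as 188 probes (highest other 12), for Platte against Dismal the only 1 of 100 with as many as 410 (highest other 1), and for any difference the only 1 of 100 with as many as 240 (highest other 5), which argues against a chance split of single fish there. The smallest share possible was 1.79% with 56 splits and 1% with 100, and the cages of the fish are unknown. A chance split is left open for Platte against Elkhorn, where 3 of 56 splits gave 8 or more and the highest other gave 120, and for Elkhorn against Dismal, where 4 of 56 gave 8 or more and the highest other gave 17. Niobrara against Dismal had 0 probes, which all 56 splits reached (highest other 5). Elkhorn against Niobrara had 0 as well, which all 10 splits reached (highest other 152), and 10 splits are too few for a share under 0.05. The split with 120 probes called many times the real count of 8, and that with 152 called many where the real split called none, and both point to a structure among arrays that the rivers do not give. The split with 152 set Elkhorn replicates 2 and 3 and Niobrara replicate 2 (75th percentile 638, 508 and 283) against dimmer arrays (199 to 236). That with 120 set Platte replicate 4 and Elkhorn replicates 2 and 3 against the others. Differences between fish and array brightness were not separated here.

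The deviations of the 16 fish from their river means were also decomposed. Over 8991 probes the first component held 21.4% of the variance within rivers. Its scores rose with the log2 75th percentile of the array, also taken from the river mean (Pearson r = 0.803, permutation p = 0.0015; Spearman rho = 0.785, permutation p = 0.00151; 100000 permutations within rivers). The second component held 12.5% and gave r = 0.262 (permutation p = 0.671) and rho = −0.0676 (permutation p = 0.856), with r = −0.318 without the 2 farthest arrays. Over these 2 components the adjusted p of the first was 0.003 for r and 0.00302 for rho. Without the 2 arrays farthest from the median brightness r was 0.703, with the slide removed it was 0.850, and on slide 1 (6 arrays) it was 0.931, while the other slides held 5 arrays each. The loadings of the first component correlated with the difference between the impact classes at r = 0.166 across probes, which are not independent replicates.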
